A study of Mus musculus with 4 samples.

How the data were processed

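RNA-seq was performed on the dentate gyrus of the hippocampus of C57BL/6 mice at postnatal day 14, from 2 wild-type (WT) animals and 2 animals with a conditional knockout of Eed (Eed cKO). Eed encodes a core subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. Per the labels' protocols, the tissue was flash frozen, RNA was extracted with Trizol and libraries were made with an Illumina kit, and the series' design text names the BGISEQ-500 as the sequencer. The labels name no driver of the deletion, deleted exons, sex, litter or batch. The series' design text calls the replicates biological, and the groups were taken from the sample titles.

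The authors deposited a single table of 18042 genes that compares the groups. HISAT2 2.1.0, DESeq2 1.2.0 and the genome build GRCm38 are named per the submitters' processing notes. The read counter, its strand setting and the annotation are not given in the sources used here. Per the file headers, the authors' table holds a mean normalized signal for each group and over all libraries, a log2 fold change of Eed cKO over WT with its standard error, a Wald score, a p-value and an adjusted p-value. The deposited mean signal over all libraries equals the mean of the group signals in every gene, to a relative difference of 8.25e-15. The deposited adjusted p-value is 1 for the 2999 genes whose mean signal is at most 8.98 and for no other gene, so it was treated as missing there. The deposited adjustment covered 17009 features, more than the 15043 genes listed with an adjusted p below 1, so the table holds part of the features the authors tested.

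Each deposited group signal is the mean of 2 counts, each divided by its library's size factor. A group's values therefore lie on a lattice of 2 steps, 0.495 and 0.498 for WT and 0.499 and 0.502 for Eed cKO. Whole read counts of both libraries of each group were recovered from these steps for 100% of the 18042 genes, within a tolerance of 1e-08. The largest residual was 4.07e-10 in WT and 6.11e-10 in Eed cKO, and the smallest residual of any second-best pair of counts was 9.85e-07 and 1.32e-06. The recovered libraries are called WT A, WT B, Eed cKO A and Eed cKO B. The group of each is that of the deposited column, but which replicate number in the titles it belongs to is unknown. DESeq2 1.42.0 run on the recovered counts gave log2 fold changes within 6.76e-05 of the deposited ones, and shared all 1047 of the deposited calls.

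The recovered counts were divided by the size factors, which ran from 0.996 to 1.01. Since the deposited values are size-factor-normalized counts, the main test was the one chosen for that unit before the data were examined. It was limma 3.58.1 with an intensity trend on log2(normalized count + 1), for genes with at least 10 normalized counts in at least 2 libraries. Genotype was the only term. Benjamini-Hochberg adjustment ran over the 15020 genes tested, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. Errors of log2 fold changes are standard errors, and errors of normalized counts are SDs over 2 libraries. With 2 residual degrees of freedom, the estimated prior degrees of freedom were 4.00. For genes with no WT read, a lower bound of the fold was computed against a floor of 3 counts over the 2 WT libraries, or 1.49 normalized counts in the group mean. Intervals of counts are exact 95% Poisson intervals, and they and the floor cover counting error only.

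Gene lists were fixed before the data were examined, 26 to be tested and 1 of sex-linked genes as a check of the samples. They were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. camera with an estimated correlation and fry were run beside it. None of the 16 camera calls was kept with an estimated correlation. For each list, the members past the threshold are also counted adjusted over the list alone. Genes to name were set by rule before the data were examined. The rule took Eed and Sox11. It took the 6 largest changes in each direction among genes past the threshold with non-overlapping groups and a mean of at least 50 normalized counts, leaving out genes with no symbol and Gm and Rik models. It took up to 3 members of each list with the smallest p among those past the threshold, or the 1 with the smallest p where none passed. A gene taken by this rule is not reported here. Other genes named below (the sex-linked genes beside Uty, Osr1, Foxc2, Rasef, Rrm2, Aen, Ccng1, Neurod1, Dcx, Elavl4, Ntng1, Man1a, Mpped1, Crym, S100b, Dcn, Ttr, Prm1, members that changed only without a given library, and those of the lists added for the closing section) were chosen after their values were seen.

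The limma, edgeR and DESeq2 steps were tested on simulated data, with counts drawn for the real genes at the real depth and 50 genes changed at each of 4 sizes. In the simulation, limma tested 15067 genes. It recovered 30% of those changed by a log2 fold of 0.5, 84% at 1, 100% at 2 and 98% at 3. It made 177 calls, of which 21 were false. This share is larger than the adjusted p threshold is meant to allow, so the calls below may hold more false ones than it implies. All changed genes had a mean of at least 50 normalized counts, and recovery was not split by mean count. The recovery therefore holds for such genes only and does not show how well genes of lower count were recovered. Alternatives fixed beforehand were DESeq2's Wald test, median centring, no filter, a stricter filter of 50, pseudocounts of 0.1 and 5, leaving out each library, a fold threshold and other adjusted p thresholds. Alternatives added after the data were seen were edgeR 4.0.16 (quasi-likelihood test on the recovered counts, with TMM or RLE scaling, on all libraries and leaving out each), the authors' deposited comparison and a term for the library with Xist reads. edgeR called 986 of 15047 genes. Gene symbols are those of the deposited table, except 24 that had been stored as dates and were replaced through their Ensembl identifiers. Coordinates come from the GENCODE M21 annotation of GRCm38, which holds 18030 of the 18042 identifiers. Analyses used R 4.3.3 and Python 3.11.15 with scipy 1.17.1.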

Results

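To find which transcripts depend on Eed in the young dentate gyrus, the region of the hippocampus that holds granule neurons and their progenitors, RNA was compared between 2 WT and 2 Eed cKO mice at postnatal day 14. The recovered libraries held 17789587 (WT A), 17345946 (WT B), 17433769 (Eed cKO A) and 17263273 (Eed cKO B) counts over 18042 genes. Between 17421 and 17634 genes had at least 1 count in a library, and mitochondrially encoded genes took between 5.07% and 6.13% of counts. The libraries differed in ways the labels do not give. Xist, which is transcribed from the inactive X chromosome of females, had 3809 counts in Eed cKO A and between 8 and 11 in the other libraries. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had between 0 and 1 count in Eed cKO A and between 167 and 850 in the other libraries, so the Eed cKO group joined a female-like and a male-like library while both WT libraries were male-like. None of these 5 genes passed in limma (0 at an unadjusted p under 0.05) or edgeR (1 at an unadjusted p under 0.05), and DESeq2 called Xist. For Uty, the member with the smallest p in limma, the adjusted p was 0.308. Ttr, a transcript abundant in the choroid plexus, had 110 counts in WT B against 33234 in WT A, 35706 in Eed cKO A and 23697 in Eed cKO B.

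**Figure D1:**
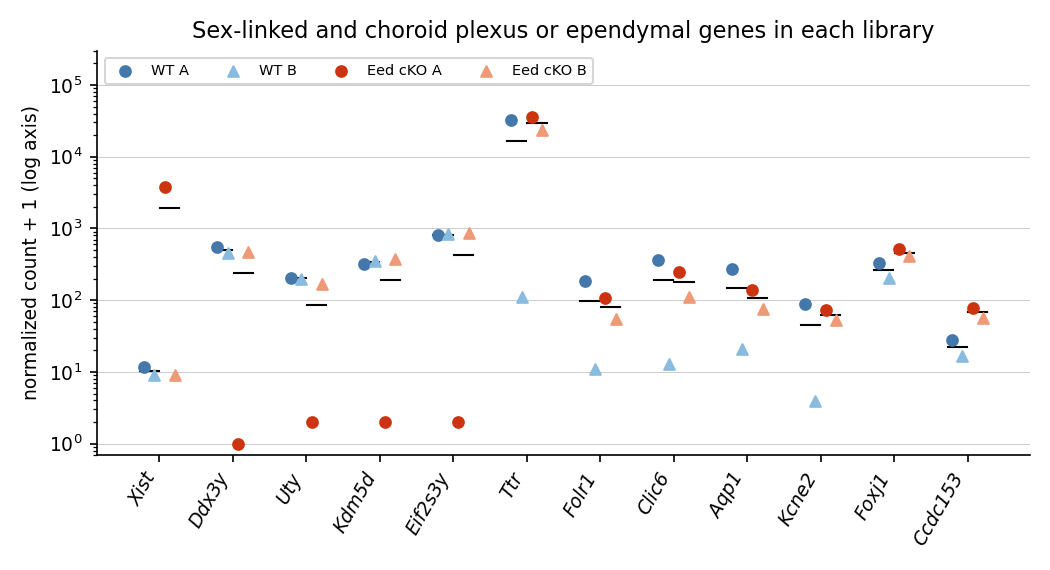
Normalized counts plus 1 (log axis) of sex-linked genes and of choroid plexus or ependymal genes, with a point for each of the 4 libraries and a black bar at each group mean. Eed cKO A stands apart in Xist (3809 counts) and the Y-linked genes (0 to 1 count), and WT B in Ttr (110 counts).

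Eed itself (ENSMUSG00000030619; GRCm38 chromosome 7, 89954654 to 89980983, minus strand, protein coding) was lower in both Eed cKO libraries. It had 251 and 301 counts in WT A and WT B against 133 and 142 in Eed cKO A and Eed cKO B. Its mean fell from 274 ± 36.3 to 138 ± 6.96 normalized counts (SD, n = 2), which is 50.2% of WT (limma, log2 fold change -0.98 ± 0.14, adjusted p = 0.0189). The count covers the whole gene, and the deleted part is not given, so reads from undeleted exons and from cells without the deletion are included. Across the transcriptome, 967 of 15020 genes tested passed an adjusted p of 0.05, of which 532 were higher and 435 lower in Eed cKO. The groups did not overlap in any of the 967, while 56.8% of all tested genes had non-overlapping groups and chance alone gives 33.3%. A log2 fold change of at least 1 in size was reached by 231 of the higher and 132 of the lower genes.

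The call for Eed and all others were lost in limma when either Eed cKO library was left out, with 0 genes past the threshold in each case and 2165 (without Eed cKO A) and 1989 (without Eed cKO B) at an unadjusted p under 0.05. With edgeR, 185 genes passed without Eed cKO A and 44 without Eed cKO B. A term for the library with Xist reads likewise left 0 genes past the threshold in limma, with 2145 at an unadjusted p under 0.05.

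**Figure D2:**
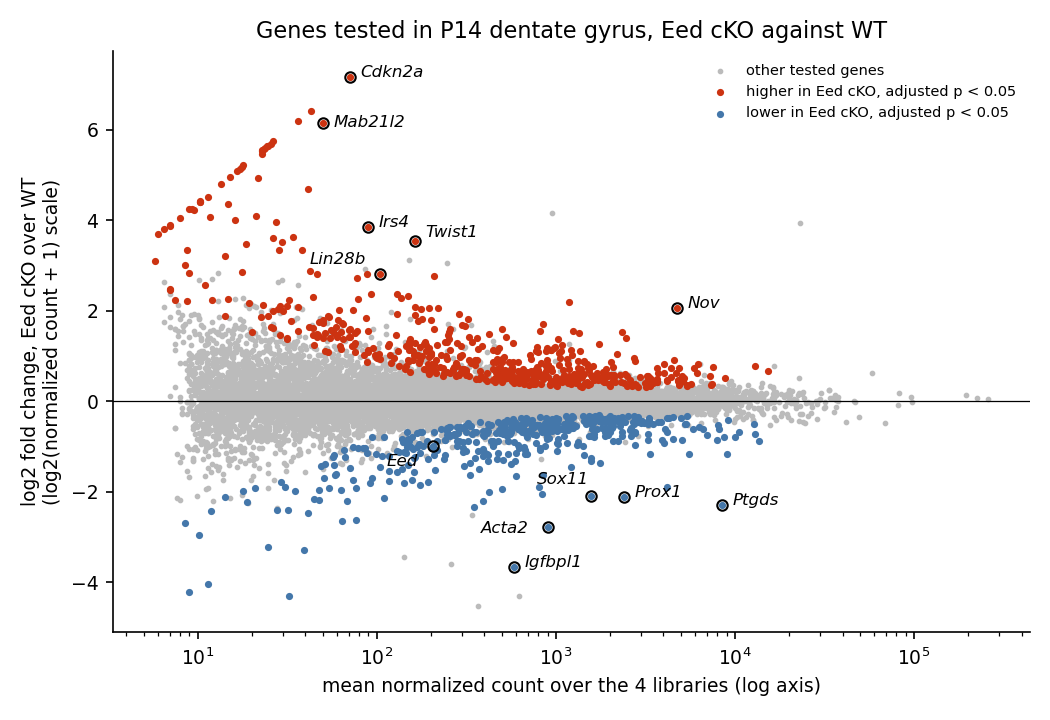
Log2 fold change of Eed cKO over WT against the mean normalized count over the 4 libraries (log axis) for the 15020 genes tested, with the 532 higher (red) and 435 lower (blue) genes past an adjusted p of 0.05 in limma. Cdkn2a (fitted log2 fold change 7.16, which depends on the pseudocount since WT had no read) lies highest and Igfbpl1 (-3.68) is the lowest of the labelled genes.

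Genes of the Hox clusters, which pattern the body axis and are normally silent in the forebrain, were read in the Eed cKO libraries and almost absent from WT. The list names 39 Hox genes, of which the deposited table holds 34. All 34 had at least 1 count in each Eed cKO library. Their summed counts were 732 (95% Poisson interval 680 to 787) in Eed cKO A and 696 (645 to 750) in Eed cKO B, against 3 (0.619 to 8.77) in WT A and 5 (1.62 to 11.7) in WT B. All 20 members with enough counts to be tested rose, also adjusted over the list alone. They came from each of the 4 clusters and included all 4 genes of paralogue group 13. With WT counts this low, the filter admitted a Hox gene only with at least 10 normalized counts in both Eed cKO libraries. It thus fixed the direction of the 20, and of their median and camera result, while the summed counts cover all 34. Every gene in the deposited table had at least 3 counts over the 4 libraries. With so few WT reads, the presence of most Hox genes in it thus also rested on Eed cKO reads. Hoxd8 (chromosome 2, 74704615 to 74707933) reached 72.6 ± 5.27 normalized counts (SD, n = 2) with no WT read, at least 48.7-fold higher than the WT floor (limma adjusted p = 0.00488). Hoxc4 was at least 35.2-fold and Hoxb6 at least 30.9-fold higher (adjusted p = 0.00569 and 0.00595). The median log2 fold change of the list was 4.87, or 4.27 with its 18 members without WT reads at their bounds. camera placed the list above other genes (adjusted p = 2.56e-21), with adjusted p = 0.372 with an estimated correlation. Hox transcripts overlap each other and antisense transcripts, and the strand setting of the counting is not known, so the share of reads due to each Hox gene is uncertain. In limma 0 of the 20 passed without either Eed cKO library, with all 20 at an unadjusted p under 0.05 in each case. Without Eed cKO A, edgeR called 8 of 17 tested Hox genes, and without Eed cKO B it called 0 of 18, with all 18 at an unadjusted p under 0.05.

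**Figure D3:**
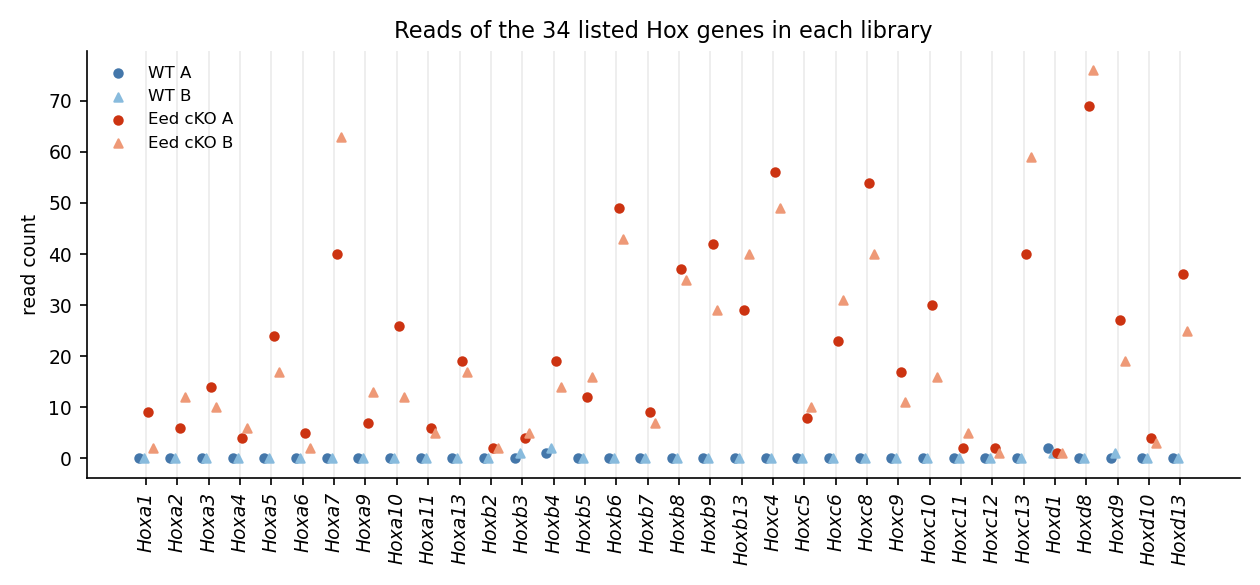
Counts of the 34 listed Hox genes, ordered by cluster and paralogue group, with a point for each of the 4 libraries. WT libraries lie between 0 and 2 counts at every gene, and Hoxd8 is highest, with 69 and 76 counts in Eed cKO A and Eed cKO B.

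Some developmental transcription factors outside the Hox clusters rose as well. Of 63 tested members, 21 rose, 2 fell and 40 did not pass, or 31 higher and 3 lower adjusted over the list alone. Vax2, a homeobox factor of the ventral eye and forebrain, had 47 and 51 counts in Eed cKO and none in WT, at least 32.9-fold higher. Pax1 was at least 22.2-fold and Gata4, a factor of heart and endoderm, at least 30.8-fold higher. Gata4 had unequal Eed cKO libraries (63 counts in Eed cKO A and 29 in Eed cKO B). Twist1, a mesenchymal factor, rose from 25.3 ± 10.4 to 303 ± 110 normalized counts (SD, n = 2; limma adjusted p = 0.00966). The members that fell were Osr1, to 51.1% of WT, and Foxc2, with 67 and 86 counts in WT against 15 and 23 in Eed cKO. The median log2 fold change was 0.90, and camera gave adjusted p = 3.59e-10, with adjusted p = 0.372 with an estimated correlation. Most of the higher members, though not Twist1, had fewer than 10 normalized counts in both WT libraries. The filter admitted these only with at least 10 normalized counts in both Eed cKO libraries, so it fixed their direction. The median and the camera result thus rest partly on this selection. With the stricter filter, which selects in the same way at a higher limit, camera gave adjusted p = 0.00623. Among all tested genes, 30 had no read in either WT library, and all 30 were called higher in Eed cKO. The filter on low counts admits such a gene only with at least 10 normalized counts in both Eed cKO libraries, so it fixed their direction. These were 18 Hox genes, 6 other listed factors and 6 genes outside both lists. In the opposite direction, 1 tested gene had no read in either Eed cKO library. It was Rasef, with 16 and 20 WT counts, and it was at least 11.9-fold lower (limma adjusted p = 0.0143). Without Eed cKO A, edgeR called 8 factors higher, and without Eed cKO B it called Twist1 alone. In limma 0 passed without either Eed cKO library (29 and 31 at an unadjusted p under 0.05), and without WT B the call for Foxc2 was lost.

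Some inhibitors of cyclin-dependent kinases rose, led by Cdkn2a, which encodes the Ink4a and Arf tumour suppressor proteins. Cdkn2a (ENSMUSG00000044303; chromosome 4, 89274471 to 89294653, minus strand) had no WT read and 135 and 149 counts in Eed cKO A and Eed cKO B. It was at least 95.3-fold higher (limma adjusted p = 0.00334). Its fitted log2 fold change, 7.16 ± 0.36, depends on the pseudocount and was the largest of the called genes with a mean of at least 50 normalized counts. Its neighbour Cdkn2b rose from 26.8 ± 4.33 to 94.6 ± 0.300 normalized counts and Cdkn1a from 593 ± 111 to 1295 ± 82.9 (SD, n = 2; limma adjusted p = 0.0141 and 0.0131). These 3 of 7 members rose and none fell, or 4 higher and 1 lower adjusted over the list alone. Of 15 p53 pathway targets, 5 rose and 10 did not pass, or 7 higher adjusted over the list alone. Eda2r rose 7.51-fold, Pmaip1, which promotes apoptosis, 4.98-fold and Phlda3 2.21-fold, and Aen and Ccng1 were the others. camera gave adjusted p = 0.0142 for the inhibitors and 0.000106 for the p53 targets, with adjusted p = 0.536 and 0.372 with an estimated correlation. Without Eed cKO A, edgeR called 2 inhibitors and 3 p53 targets higher, and without Eed cKO B it called Cdkn2a and no p53 target (7 at an unadjusted p under 0.05).

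Among 36 cell cycle genes, 3 fell, 1 rose and 32 did not pass, or 4 lower and 1 higher adjusted over the list alone. The replication licensing genes Mcm7 and Mcm6 fell to 54.2% and 54.0% of WT and Rrm2, a subunit of ribonucleotide reductase, to 48.5%. Ccnd1, the G1 cyclin D1, rose 2.27-fold, from 547 ± 81.6 to 1242 ± 201 normalized counts (SD, n = 2; limma adjusted p = 0.0141). The list's median was -0.24, and camera gave adjusted p = 0.0087 for a lower list, with adjusted p = 0.587 with an estimated correlation. Without WT B, 0 members passed as lower in limma (4 at an unadjusted p under 0.05, and 2 called by edgeR) and the camera call was lost (adjusted p = 0.0595). Without WT A, the lower members were Bub1b, Mcm6 and Mcm7. The camera call was also lost without Eed cKO B (adjusted p = 0.121).

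Most of the granule neuron lineage markers past the threshold fell. Igfbpl1, a marker of newborn neurons (chromosome 4, 45809468 to 45826923, minus strand), fell from 1086 ± 124 to 84.0 ± 8.13 normalized counts (SD, n = 2), or 7.74% of WT (limma, log2 fold change -3.68 ± 0.13, adjusted p = 0.00209). Sox11, a transcription factor of immature neurons (chromosome 12, 27334264 to 27342574, minus strand), fell from 2572 ± 270 to 597 ± 34.9, or 23.2% (adjusted p = 0.00329). Prox1, the homeobox factor that marks granule neurons (chromosome 1, 190118035 to 190170714, minus strand), fell from 3908 ± 790 to 893 ± 42.1, or 22.8% (adjusted p = 0.00488). Of 18 immature granule neuron markers, 7 fell, 1 (Elavl4, a neuronal RNA-binding protein) rose and 10 did not pass, or 9 lower and 6 higher adjusted over the list alone. Neurod1 and Dcx were among those that fell, to 36.2% and 51.2% of WT. Of 18 mature granule neuron markers, 7 fell, 1 (Ntng1) rose and 10 did not pass, or 12 lower and 1 higher adjusted over the list alone. Lct fell to 21.7%, Dsp to 43.8% and Sema5a to 58.8% of WT (limma adjusted p = 0.00329, 0.00798 and 0.0109).

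The medians of the immature and mature lists were -0.25 and -0.61, and camera gave adjusted p = 0.0147 and 5.36e-06, with adjusted p = 0.562 for each with an estimated correlation. The Elavl4 call was lost in limma without WT A, where Nnat passed as higher, and without WT B, where Marcksl1, Ncam1 and Stmn1 did. Without Eed cKO A, edgeR called 6 immature and 2 mature granule markers lower, and without Eed cKO B it called Igfbpl1, Sox11 and Lct.

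Earlier stages of the lineage changed in few members. Of 10 intermediate progenitor markers, Eomes and Mfap4 fell, to 23.5% and 43.7% of WT, and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.0472, and adjusted p = 0.562 with an estimated correlation). This camera call was lost without WT B, without Eed cKO B and with a filter of 50 counts (adjusted p = 0.187, 0.165 and 0.0644). Eomes had 150 and 209 counts in WT against 58 and 26 in Eed cKO (limma adjusted p = 0.0341). Of 20 neural stem cell and radial glia-like cell markers, Tfap2c rose 2.43-fold, Emx2 and Lpar1 fell to 70.2% and 59.2%, and 17 did not pass, or 2 higher and 4 lower adjusted over the list alone. The median of this list was -0.25 and its mean 0.03, so they differed in sign, and camera's direction was downward (adjusted p = 0.25). The Emx2 call was lost with DESeq2 and without either WT library, and those of Lpar1 and Eomes without WT B. Without WT A, Hes1, Tfap2c and Wnt8b passed as higher and Id4, Lpar1, Nr2e1 and Prom1 as lower, and without WT B, Pax6 and Tfap2c passed as higher and none as lower.

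**Figure D4:**
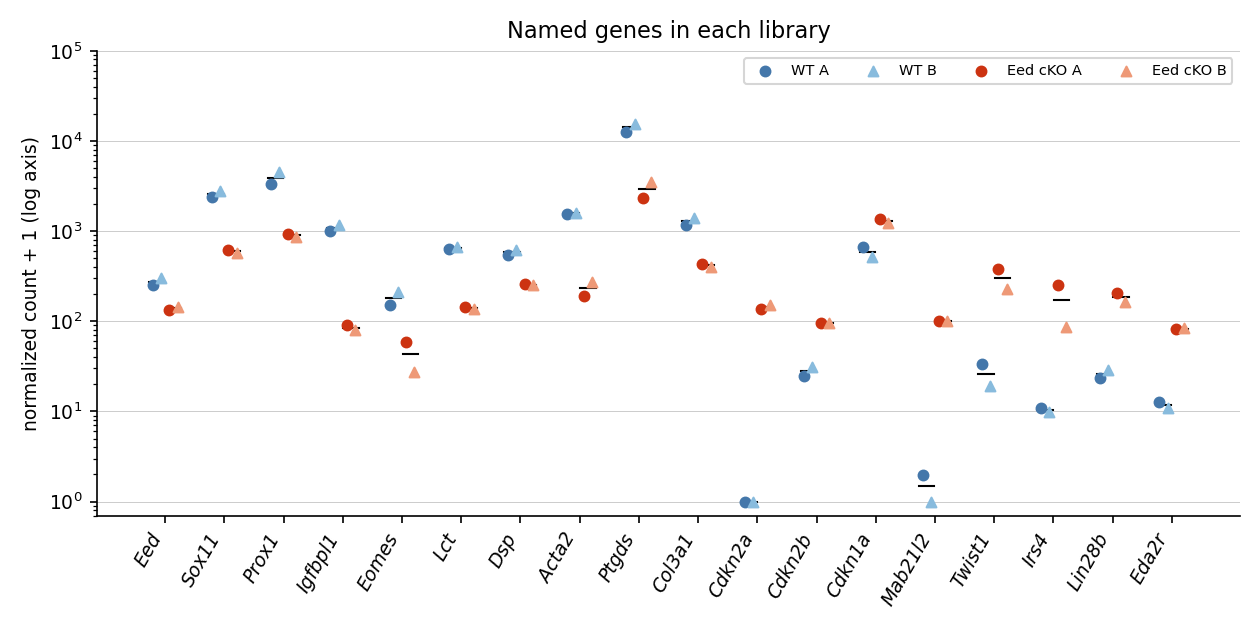
Normalized counts plus 1 (log axis) of 18 named genes, with a point for each of the 4 libraries and a black bar at each group mean. Igfbpl1 falls from a mean of 1086 to 84.0 normalized counts and Cdkn2a rises from 0 to 142.

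Some markers of other neurons rose and a few fell. Of 18 GABAergic interneuron markers, all had a positive fold change, 3 rose and 15 did not pass, or 13 higher adjusted over the list alone. The peptide gene Sst rose from 2913 ± 388 to 5160 ± 662 normalized counts (SD, n = 2; limma adjusted p = 0.0212), Dlx2 1.67-fold and Erbb4 1.45-fold. camera gave adjusted p = 1.68e-07, with adjusted p = 0.372 with an estimated correlation, and the Dlx2 and Erbb4 calls were lost without WT B, where Npy, Reln and Sst passed. Without WT A, 6 passed (Dlx1, Dlx2, Erbb4, Lhx6, Slc32a1 and Sst). Of 15 CA pyramidal neuron markers, 5 rose, 1 fell and 9 did not pass, also adjusted over the list alone (camera adjusted p = 0.232). Nov, a secreted matrix protein, rose 4.09-fold, Ociad2 1.47-fold, and Man1a, Mpped1 and Crym between 1.36-fold and 1.54-fold. Wfs1, an endoplasmic reticulum protein, fell from 4645 ± 932 to 2060 ± 167 normalized counts (SD, n = 2; limma adjusted p = 0.014). Without WT B, 4 CA markers passed as lower, the others being Dkk3, Grik4 and Iyd. Of 10 thalamic neuron markers, the homeobox gene Lhx9 rose 3.25-fold, from 400 ± 74.2 to 1300 ± 147 normalized counts (SD, n = 2; limma adjusted p = 0.00679), and Plekhg1 fell to 68.5%. The other 8 did not pass, or 2 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.114), and without WT B, 4 passed as higher (Lhx9, Lef1, Ramp3 and Slc17a6) and Prkcd in place of Plekhg1 as lower, with camera adjusted p = 0.0317 for a higher list. With all libraries and an estimated correlation, the adjusted p of this list was 0.562.

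Among glia, some astrocyte markers fell. Of 16 tested, 5 fell, 1 (S100b, 1.38-fold) rose and 10 did not pass, or 11 lower and 1 higher adjusted over the list alone. The neurotensin receptor gene Ntsr2 fell to 51.1% of WT and the gap junction genes Gjb6 and Gja1 to 52.4% and 55.1% (limma adjusted p = 0.0109, 0.0164 and 0.0171). camera gave adjusted p = 2.4e-05, with adjusted p = 0.562 with an estimated correlation, and 9 members passed as lower without WT A. None of 16 oligodendrocyte markers passed in limma, edgeR or DESeq2, also adjusted over the list alone, and 2 had an unadjusted p under 0.05 in limma. Opalin, with the smallest p, had 132 ± 7.57 and 82.6 ± 2.48 normalized counts in WT and Eed cKO (SD, n = 2; limma adjusted p = 0.0649; camera adjusted p = 0.25 for the list). Of 11 oligodendrocyte precursor markers, Sox10 rose 1.35-fold and 10 did not pass, or 4 higher adjusted over the list alone. Of 15 microglia markers, Trem2 rose 1.47-fold and 14 did not pass, or 2 higher adjusted over the list alone. camera gave adjusted p = 0.0087 for the precursor list and 0.0197 for the microglia list, with adjusted p = 0.562 and 0.587 with an estimated correlation. Both camera calls were lost without WT A (adjusted p = 0.106 and 0.446), and that of the microglia list also without Eed cKO B (0.0915). Without WT A, Ptprz1 passed as lower, and without WT B, Pdgfra as higher. The Trem2 call was lost with DESeq2 and without either WT library, and without WT B the microglia members past the threshold were C1qa, C1qb, C1qc and Cx3cr1. Without WT A, 0 microglia markers passed in limma, with 5 at an unadjusted p under 0.05, and edgeR called 1 lower. Without Eed cKO A, the oligodendrocyte list was lower by camera (adjusted p = 0.0114), and with all libraries and an estimated correlation its adjusted p was 0.698.

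Most markers of meningeal fibroblasts fell, as did a smooth muscle gene of vessel walls. Of 10 meningeal fibroblast markers, 9 fell and 1 rose, also adjusted over the list alone. The collagen genes Col3a1 and Col1a2 fell to 32.2% and 39.6% of WT and the anion transporter gene Slc22a6 to 37.0% (limma adjusted p = 0.00488, 0.00605 and 0.00798). Dcn, which encodes the proteoglycan decorin, rose from 809 ± 94.6 to 1644 ± 16.3 normalized counts (SD, n = 2; limma adjusted p = 0.00798). The list's median was -1.30, and camera gave adjusted p = 1.68e-07, with adjusted p = 0.536 with an estimated correlation. Without Eed cKO A, edgeR called 5 of them lower, and without Eed cKO B it called 0 (9 lower at an unadjusted p under 0.05). In limma the call for Lum was lost without WT A, and those for Lum, Aldh1a2 and Igf2 without WT B. Of 14 vascular cell markers, Acta2, the smooth muscle actin, fell and 13 did not pass, or 2 lower adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.598 with an estimated correlation). Without WT A, Cdh5, Pecam1 and Vtn passed as lower beside Acta2, and the camera call was lost without WT B and without Eed cKO B (adjusted p = 0.512 and 0.0789).

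Of 12 choroid plexus and ependymal markers, all had a positive fold change, and Ccdc153, an ependymal gene, rose from 21.3 ± 7.64 to 66.5 ± 14.6 normalized counts (SD, n = 2; limma adjusted p = 0.0465). The other 11 did not pass, also adjusted over the list alone. camera gave adjusted p = 0.0175, with adjusted p = 0.598 with an estimated correlation. This list followed the low choroid plexus reads of WT B: without WT A 11 members passed as higher, and camera gave adjusted p = 8.89e-11. Without WT B 0 passed in limma (6 at an unadjusted p under 0.05), edgeR called 2 lower and camera's direction turned downward (adjusted p = 0.346). The camera call was also lost without Eed cKO A (adjusted p = 0.116), and the Ccdc153 call without WT B and with a filter of 50 counts. None of 5 erythroid genes passed in limma or edgeR, also adjusted over the list alone, with 3 at an unadjusted p under 0.05, and DESeq2 called 1 lower. Alas2, with the smallest p, had 111 ± 41.2 and 51.0 ± 5.44 normalized counts in WT and Eed cKO (SD, n = 2; limma adjusted p = 0.0922). camera gave adjusted p = 0.0472 for a lower erythroid list, with adjusted p = 0.562 with an estimated correlation, and the globin genes have near-identical copies that share reads. This camera call was lost without WT B, without Eed cKO B and with a filter of 50 counts (adjusted p = 0.303, 0.121 and 0.067), and Alas2 and Hbb-b1 passed as lower without WT A.

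**Figure D5:**
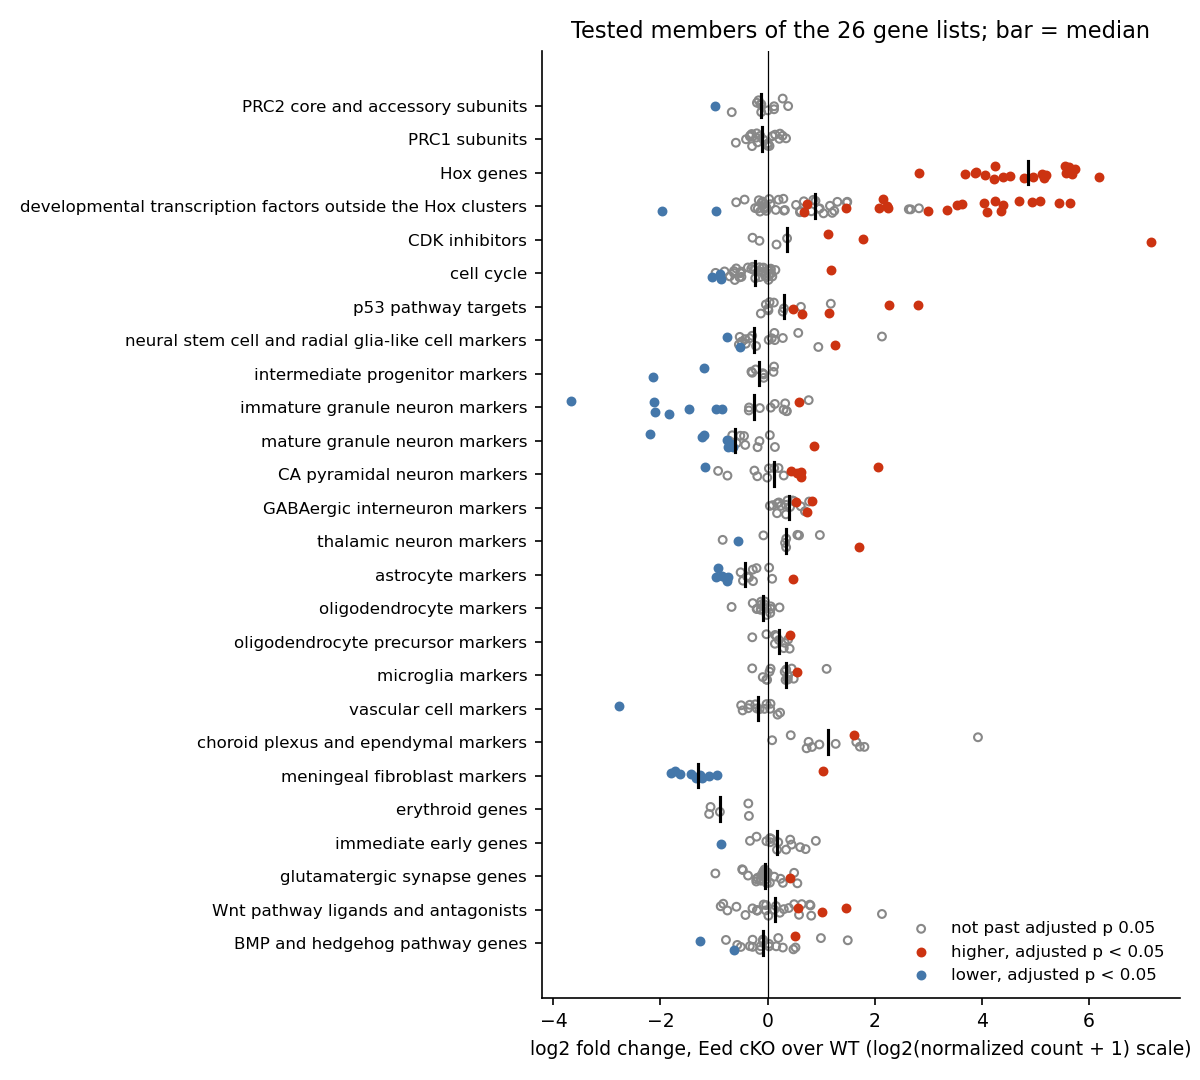
Log2 fold change of Eed cKO over WT for each tested member of the 26 gene lists, with filled points past an adjusted p of 0.05 in limma (red higher, blue lower), open points for the others and a black bar at each list's median. The Hox genes lie farthest right (median 4.87) and the meningeal fibroblast markers farthest left (median -1.30).

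Among called genes with a mean of at least 50 normalized counts, Gm and Rik models aside, those with the largest changes lay partly outside these lists. Mab21l2, a developmental gene of the eye and midbrain, had 1 and 0 counts in WT against 100 and 99 in Eed cKO (limma adjusted p = 0.00551). Irs4, an insulin receptor substrate, rose 18.0-fold with unequal Eed cKO libraries (255 counts in Eed cKO A and 86 in Eed cKO B; adjusted p = 0.0145). Lin28b, an RNA-binding regulator of let-7 microRNAs, rose 7.26-fold and Gabrq, a GABA-A receptor subunit, 6.73-fold (limma adjusted p = 0.00574 and 0.0259). Gabrq had unequal libraries, with 13 and 33 counts in WT A and WT B against 189 and 119 in Eed cKO A and Eed cKO B. Irs4 and Gabrq lie on the X chromosome, where 35 of 523 tested genes were called higher and 9 lower, against 532 and 435 of 15020 overall. Both had more counts in Eed cKO A, the female-like library, and a part of sex in their rise was not tested. Cdkn2a and Twist1 completed the 6 largest rises within this limit. Some called genes of lower mean count rose more than most of these, such as Hoxd8 (fitted log2 fold change 6.20). Within the same limit, the largest falls after Igfbpl1 were in Acta2, Slc47a1, Serpind1, Myh11 and Ptgds, while Rasef, of lower mean count, fell further than these. Acta2 fell to 14.7% of WT and Serpind1, which encodes heparin cofactor II, to 15.5%. Slc47a1, an organic cation exporter, fell to 15.8%, with unequal libraries (77 and 146 counts in WT, 25 and 10 in Eed cKO). Myh11, the smooth muscle myosin heavy chain, fell to 19.7% and Ptgds, the prostaglandin D synthase abundant in the meninges, from 14089 ± 2073 to 2914 ± 863 normalized counts (SD, n = 2; limma adjusted p = 0.00785). The Slc47a1 call was lost without WT B.

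No Polycomb subunit other than Eed passed in limma with all libraries, and signalling and synaptic genes changed in few members. Of 12 tested PRC2 subunits Eed fell and 11 did not pass, also adjusted over the list alone, and Ezh2 passed as lower as well without WT A. None of 20 PRC1 subunits passed in limma, edgeR or DESeq2, also adjusted over the list alone, with 10 at an unadjusted p under 0.05 in limma. camera gave adjusted p = 0.25 and 0.232 for these lists. Of 28 Wnt ligands and antagonists, Wnt4, Wnt9a and the antagonist Wif1 rose 1.49-fold, 2.03-fold and 2.80-fold and 25 did not pass, or 9 higher and 1 lower adjusted over the list alone. For this list camera gave adjusted p = 0.183, or 0.0177 with a filter of 50 counts, and 0.562 with an estimated correlation and the usual filter. fry called it higher (adjusted p = 0.0271). Without WT A, Wnt4 and Wnt8b passed as higher and the Wnt9a and Wif1 calls were lost, and without WT B, Lef1, Rspo3, Wif1, Wnt4 and Wnt9a passed as higher and Dkk3 as lower. Of 22 BMP and hedgehog pathway genes, Bmp6 and Id3 fell to 41.7% and 65.2% of WT, the BMP antagonist gene Chrd rose 1.41-fold and 19 did not pass, or 3 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.448). The Id3 call was lost without either WT library. Of 28 glutamatergic synapse genes, the AMPA receptor subunit gene Gria4 rose 1.33-fold and 27 did not pass, or 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.435). Without WT A, Syt1 was also higher and Camk2b and Grm2 lower, and without WT B, Slc17a6 was also higher and Camk2b, Grin2a and Syn2 lower. Of 15 immediate early genes, Egr3 fell to 53.6% and 14 did not pass, also adjusted over the list alone (camera adjusted p = 0.256, or 0.0014 for a higher list without Eed cKO B, and 0.698 with all libraries and an estimated correlation).

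The authors' deposited table lists 1047 genes at an adjusted p below 0.05, with 561 higher and 486 lower, of which 805 were called here in the same direction and 0 in the opposite direction. In the authors' deposited table Eed has an adjusted p of 0.00197, and the log2 fold change is -2.11 for Sox11 and -3.69 for Igfbpl1. Xist is among the calls of the authors' deposited table (adjusted p = 0.0339), where its value rests on Eed cKO A.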

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

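The edgeR fits, the authors' deposited comparison and the term for the library with Xist reads were chosen after the data were seen. Of the 967 genes called by limma, 948 were shared with edgeR (986 calls), 822 with DESeq2 (1077) and 941 with median centring (986), with none in the opposite direction. edgeR with RLE scaling called 997, the stricter filter 937 and the pseudocounts of 0.1 and 5 gave 936 and 982. The share of higher calls stayed between 51.7% and 57.3% over the scalings, tests and filters. Without a filter, 473 genes passed (271 higher, 202 lower), 469 of them shared, with 18042 genes then tested. An adjusted p of 0.01 left 113 (67 higher, 46 lower), an adjusted p of 0.1 gave 1803 (946 and 857), and an absolute log2 fold change of at least 1 left 363 (231 and 132).

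Leaving out each library in turn assumes that the lone library varies like the other group's pair. In limma it gave from 0 to 1386 calls (0 to 789 higher, 0 to 597 lower), with 1386 without WT A, 955 without WT B and 0 without either Eed cKO library. In edgeR it gave 1614 without WT A (864 higher, 750 lower), 1105 without WT B, 185 without Eed cKO A (110 and 75) and 44 without Eed cKO B (24 and 20). The term for the library with Xist reads, which leaves Eed cKO B as the only Eed cKO library that counts, gave 0 calls in each direction. Without either Eed cKO library, and with this term, the residual error came from the WT pair alone. Whether the spread of that pair caused these losses was not tested.

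Eed had a log2 fold change from -1.12 to -0.85 over the libraries left out (adjusted p from 0.0173 to 0.242). Its call was lost without Eed cKO A (-0.93) and without Eed cKO B (-1.04), and with the Xist term (-0.93, adjusted p = 0.245). It was kept without either WT library (adjusted p = 0.0173 and 0.0452) and in the other settings that used all libraries (0.00185 to 0.0443). Of 61 named genes that passed, all 61 kept direction and call with median centring, edgeR and both pseudocounts, 59 with DESeq2, 43 without a filter, 56 without WT A and 49 without WT B. With the stricter filter 55 kept their call and 1 lost it. In limma 0 kept it without either Eed cKO library. None changed direction in any setting. Of the 16 list calls, 0 were kept by camera with an estimated correlation, and fry called 7 lists, 6 of them among the 16. camera called from 12 to 16 lists over the libraries left out and 14 with the stricter filter. The choroid plexus and ependymal list ran from adjusted p = 8.89e-11 (higher, without WT A) to 0.346 (lower, without WT B), and the cause was not tested beyond the low choroid plexus reads of WT B. Depth limits the low Hox genes, of which 14 had too few counts to be tested. No paired analysis was possible because the deposited columns carry no replicate numbers.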

Other observations

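The tests of meningeal, receptor and other-tissue genes were set before their values were seen, except that Isl1 had been, and the other tests here, with the lists added for them, were chosen after the result was seen. The reading of the weighed values, by 2 standard errors, was also settled after they were seen. A median counts as past its bound only beyond 2 standard errors, without which other tissue and CA tissue would be argued against and less meningeal tissue would have met its bound. Where an explanation needs groups of genes to move alike, a gap of more than 2 standard errors from 0 counts against it. Standard errors of list medians and of gaps between them are over genes. They do not measure the spread between animals, so readings that rest on them hold for the listed genes in these libraries only. Imprinted genes, which are transcribed only or mainly from the maternal or the paternal allele in at least some tissues, were called more often than other genes. Of 38 tested imprinted genes, 12 passed (31.6%), 11 of them higher and Igf2 lower, against 955 of 14982 other tested genes (6.37%; two-sided Fisher's exact test, p = 2.69e-06, odds ratio 6.78). Genes are not independent replicates, and imprinted genes lie in shared clusters. The pattern was seen before this test was chosen, and the genes seen first were kept in, so its p-value is descriptive. Peg10 rose from 527 and 332 counts in WT to 2348 and 1525 in Eed cKO, Dlk1 from 69 and 83 to 343 and 293, Magel2 from 102 and 69 to 415 and 296, and Calcr from 3 and 3 to 67 and 33. Meg3, the most abundant member, had 45454 and 47376 counts in WT and 68000 and 73688 in Eed cKO (limma adjusted p = 0.0656). A hypothesis is that loss of PRC2 may raise imprinted genes as a class, but allele-specific reads were not analysed here, and 26 of the 38 did not pass. Without either Eed cKO library, 0 passed in limma, with 14 (without Eed cKO A) and 16 (without Eed cKO B) at an unadjusted p under 0.05, and edgeR called 4 and 1.

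Of 10 smooth muscle genes, 8 fell and 2 did not pass (median log2 fold change -1.54), while none of 10 pericyte genes (median 0.06) or 14 endothelial genes (median -0.16) passed in limma. At an unadjusted p under 0.05 these were 4 pericyte and 4 endothelial genes, edgeR called 0 and 1, and DESeq2 1 and 0. Without WT A, limma called 2 pericyte and 3 endothelial genes lower. Without either Eed cKO library, limma called 0 smooth muscle genes, with 8 and 9 at an unadjusted p under 0.05, and edgeR called 3 and 2. Cnn1 had 60 and 50 counts in WT against 9 and 10 in Eed cKO, and Myl9 572 and 585 against 246 and 266. Prm1, which encodes a protamine of sperm chromatin, had 0 WT counts and 70 and 102 in Eed cKO, at least 57.8-fold higher (limma adjusted p = 0.00488).

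The fall of meningeal fibroblast and vessel wall genes was weighed against the sampling of tissue. Fewer vessels of every kind stay open as the whole cause. The smaller of the endothelial and pericyte medians lay 1.39 (standard error 0.51) above the smooth muscle median on the log2 scale. Without Acta2 and Myh11, which had been seen before, it lay 0.93 (standard error 0.42) above. The listed smooth muscle genes thus fell more than the other listed vessel genes. A gap within 0.5 was written as fitting this cause and a gap above 1 as against it. Neither gap lay beyond either bound by 2 standard errors, so they cannot decide. The first gap passed the bound of 1 by less than its error, and the second lay below that bound. In both gaps the endothelial and pericyte genes included those of the vascular list, which had been seen before too. The comparison therefore rests partly on genes already seen. Less meningeal tissue in the Eed cKO pieces stays open, because 16 further fibroblast genes had a median log2 fold change of -0.60 (standard error 0.17), too close to the bound of -0.5 to decide, and it was -0.37 without WT B, with 3 called lower and 2 higher, and -0.74 without WT A. A difference of Eed cKO A by sex is argued against as the whole cause, because the summed normalized counts of the 10 listed fibroblast markers had a ratio of Eed cKO A to Eed cKO B of 1.04 (standard error 0.02, counting error only), at 55.2% and 53.2% of the WT mean, and Acta2 had 192 and 270 counts against 1568 and 1603 in WT, while a change of gene activity in these cells was not tested.

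The reads of Hox genes and of other genes with no WT read were weighed next. Genomic DNA or unspecific reads are argued against, because summed counts of 72 olfactory, vomeronasal and taste receptor genes were alike. Their ratio of Eed cKO to WT was 1.01 (standard error 0.08, from the spread between libraries). A difference by sex is argued against too, because the summed normalized Hox counts of Eed cKO A and Eed cKO B had a ratio of 1.05 (standard error 0.06, counting error only). Tissue of another organ or of the spinal cord stays open. The 19 tested genes of liver, muscle, skin, gut and motor neurons had a median log2 fold change of 0.45 (standard error 0.22), with 1 called higher and 1 lower. The median lay below the bound of 1 written for this cause by more than 2 standard errors. It was too close to the bound of 0.5, below which it would count against the cause, to decide. It was 0.25 without WT A and 0.14 without Eed cKO B. Of 30 listed liver, muscle, skin and gut genes only 11 were tested, and of 12 motor neuron genes only 8. Loss of Eed, the biological difference that the design names, stays among the open explanations as untested.

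The fall of granule cell genes may reflect fewer granule cells, lower activity of these genes, or both. Fewer granule cells as the only change in the tissue are argued against. A lower share alone would raise the markers of all other types alike. The interneuron median instead lay 0.82 (standard error 0.16) above the astrocyte median on the log2 scale. A separate change of astrocyte genes could give this gap, so it cannot decide whether fewer granule cells explain the whole fall of granule genes. Fewer granule cells, as part or all of the cause of that fall, stay open. More CA tissue in the Eed cKO pieces stays open, because the CA pyramidal markers had a median log2 fold change of 0.12 (standard error 0.18) over members that went both ways, with Wfs1 lower and Nov higher, and it was 0.27 without WT A, -0.02 without WT B and 0.08 without Eed cKO B. A change of cell state in granule neurons was not tested apart from these.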
